A study of Mus musculus with 2 samples.

How the data were processed

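The counts used here are the deposited tables of raw UMI counts, 1 per library with 25507 gene symbols each, which the authors made per the submitters' processing notes with alignment to GRCm38. The aligner, the counter, the gene annotation and the use of strand are not given in the sources used here. Per the labels' protocols, cells were sorted for low and high Ngn3eGFP, encapsulated on the inDrop platform (1CellBio), amplified linearly as in CEL-Seq and sequenced with paired ends on a NextSeq500. The reporter transcript and Epcam were not used here. No reads were realigned, and every deposited column was used, with 0 left out.

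Cells were kept with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs, which left 528 of 535 barcodes in library 1 and 1081 of 1100 in library 2. Scrublet, run per library in scanpy 1.11.5, called 13 doublets (2.46%) and 11 doublets (1.02%), which were removed. The 2000 most variable genes, found with library as batch, less all genes of the fixed lists, gave 1864 features for 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2), with no batch correction. Clusters were named by markers written down in advance. A class needed at least 20 cells in each library to be compared. The planned comparisons of epsilon-like with alpha-like and delta-like with beta-like cells were not made, because no separate epsilon-like class formed and the delta-like class had 3 cells in library 1.

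UMIs were summed per library and class, over 46 to 264 cells and 196106 to 781751 UMIs per sum. The 10 sums of 5 classes were fitted together in edgeR 4.0.16 (R 4.3.3) by quasi-likelihood, with TMM scaling, the default filter on low counts, and class plus library as terms, which made 6 coefficients and left 4 residual degrees of freedom. Library entered as a block because both classes of every comparison come from the same 2 libraries. Genes that served as clustering features were not tested, which left 9662 genes, and p-values were adjusted by Benjamini-Hochberg at 0.05. Clustering and testing used the same cells, so genes correlated with the features can pass more easily, and count splitting was run as an alternative. The p-values measure only how class differences vary between these samples, since the library term takes up the overall difference. Each gene's spread is drawn toward a spread shared over genes, so p-values and SEs do not rest on that gene's own libraries alone. The labels do not say that the libraries come from separate animals. The SE of a log2 fold change is its absolute value over the square root of its F statistic. Folds of single libraries use a pseudocount of 1 CPM. Levels in the comparisons are CPM on TMM-scaled library sizes, and levels of markers and of classes not compared are plain CPM.

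In all, 20 gene lists with 776 members were written down in advance and tested with camera (limma 3.58.1) with a preset correlation of 0.01 and with an estimated correlation, on log CPM with a prior count of 2, with adjustment over 100 tests. Of these tests 46 passed with the preset correlation, and 3 of the 46 with the estimated correlation. In 13 of the 100 tests the median, the mean or the test direction of the list differed in sign, and 0 of those 13 passed by camera. Counts adjusted over the list alone take the p-values of the list's members as the whole family. DESeq2 1.42.0 was run as a second tool, and its adjusted p was missing for 30 of the 130 named results, which were left as missing. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

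The filters, classes, comparisons, lists, tests and alternatives were chosen before the data were examined, except where the text says otherwise. Genes were named by a rule fixed with them: per comparison, the 14 list members with the lowest adjusted p, at most 2 per list, and the 6 largest rises and 6 largest falls among other genes with at least 50 CPM in the higher class and no Gm or Rik symbol. All had to pass the test with the same sign in both libraries. That made 130 results for 99 different genes, of which not all are given in the text. Further list members given as examples were picked after their values were seen. Positions are from GENCODE M21 on GRCm38, which held 24334 of the 25507 symbols (95.4%) and 97 of the 99 named genes, with Slmo1 and Cyr61 not found. Exons of 33 of them overlap another gene. On the same strand these include Cdc14b, Rps3, Stmn1 and Tmsb15b1. On the other strand they are Abi3, Adamts9, Atp1b1, Atp2a2, Baiap3, Bicc1, Cabp7, Cacna1s, Cage1, Cdc42ep1, Cdkn1a, Cnih2, Gnas, Krt90, Nkx2-2, Oxa1l, Palm3, Plch2, Rpl28, Sox4, Spns2, Ssr2, St5, Syndig1l, Tead2, Wnk3, Zfp54 and Zfp703, where levels are uncertain because the use of strand in counting is not given.

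A self-test drew simulated class sums from a mean profile shared by all classes, with the spread that edgeR had estimated and no library effect. Known changes were put into the simulated beta-like sums, which were tested against the alpha-like sums with 8974 genes. A 2-fold change was recovered for 20 of 42 genes at 50 CPM or more (47.6%) and for 1 of 58 below that level (1.72%). A 4-fold change was recovered for 52 of 54 (96.3%) and 23 of 46 genes. Of 98 calls 2 were false. In alpha-like against Fev+ endocrine precursor-like cells, with no gene changed, edgeR made 0 calls. A gene not called here may therefore still differ by 2-fold. The simulated sums passed through no clustering, so false calls from clustering and testing the same cells were not measured.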

Results

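Pancreatic cells of wild-type mouse embryos at stage E14.5, which the labels call islet cells, were profiled by single-cell RNA sequencing in 2 libraries. The cells had been flow-sorted for low and for high fluorescence of Ngn3eGFP, a green fluorescent reporter of Neurog3. Neurog3 encodes the transcription factor that starts endocrine differentiation in the pancreatic epithelium. Droplets were made on the inDrop platform, which tags each cell with a barcode and each captured RNA molecule with a unique molecular identifier (UMI). Both libraries belong to 1 group, wild type, and are called library 1 and library 2 after their replicate numbers. The labels do not say whether they came from separate embryos or litters. The p-values given here therefore measure only how class differences vary between these 2 samples, a spread that may be technical. The fit draws each gene's spread toward one shared over genes, so an SE can be smaller than the gap between a gene's 2 libraries. The labels also do not say which cells came from which gate, and the gate can set the shares of the cell classes.

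Library 1 held 535 barcodes with 1910588 UMIs in all, a median of 3244 UMIs and 1943 genes per barcode. Library 2 held 1100 barcodes with 3425983 UMIs, a median of 2828.5 UMIs and 1751.5 genes. After filters and doublet removal 515 and 1070 cells were kept, 1585 in all. The counts of the 2 libraries, summed over the classes compared below, gave a chi-square of 3.31 per degree of freedom over 12654 genes. The shares of these classes also differ between the libraries. Within each class compared here, the libraries' log2 CPM correlated across genes with Pearson's r of 0.845 to 0.916, and 92.0% to 98.0% of genes at 50 CPM or more lay within 2-fold of each other. Genes are not independent replicates, so no p-value goes with these correlations.

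Clustering gave 10 clusters, and 9 of them were named by markers, which made 8 classes. Levels are in CPM, counts scaled to the same total for every class and library. Trunk/duct-like cells, which resemble the bipotent epithelium that forms ducts and endocrine progenitors, were marked by Spp1 at 3304 CPM. Neurog3+ endocrine progenitor-like cells held Neurog3 at 3147 ± 464 CPM (mean ± SD, n = 2 libraries), against 365 ± 39.0 CPM in trunk/duct-like cells and 236 ± 48.4 CPM in Fev+ endocrine precursor-like cells. The last class, a later stage than the Neurog3 peak, was marked by the transcription factor gene Fev at 747 CPM. Alpha-like cells held the glucagon gene Gcg at 7355 ± 1386 CPM, and with it the ghrelin gene Ghrl at 2317 ± 181 CPM, Ppy at 744 ± 271 CPM and Pyy at 8164 ± 1035 CPM. At least 1 Gcg UMI was found in 54.4% of the alpha-like cells of library 1 and 46.4% of those of library 2, against 33.3% and 17.8% of acinar/tip-like and immune-like cells, so the class mean rests on part of its cells. Beta-like cells held the insulin genes Ins1 and Ins2 at 18158 ± 1298 and 18459 ± 1969 CPM, with an Ins1 UMI in 97.8% and 94.9% of cells, against 16.7% and 7.36% of acinar/tip-like and immune-like cells. Delta-like, acinar/tip-like and immune-like clusters were marked by Sst, Cpa1 and Csf1r, among others, and a small cluster with mesenchymal and endothelial genes stayed unnamed. No separate epsilon-like cluster formed. Ghrl, Ppy, Pyy and Peg10, written down as markers of other classes, were among the 10 leading genes of the alpha-like cluster, so that class is mixed in its markers. Trunk/duct-like cells came from 2 clusters, and the 10 leading genes of the smaller one included cycle genes and no marker. The marker genes were used to name the clusters, and their levels are no test of a difference.

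**Figure D1:**
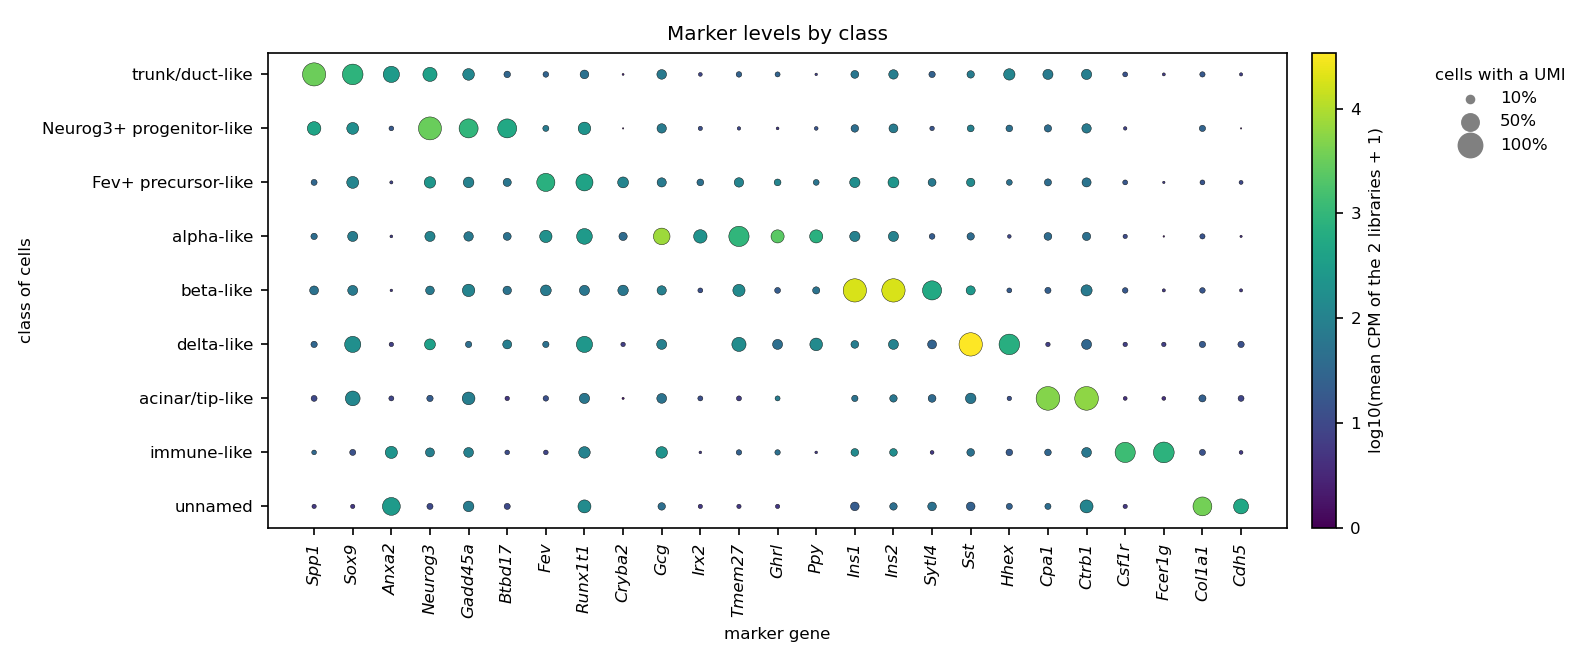
Levels of marker genes in the classes of cells. The vertical axis gives 8 named classes and the unnamed cluster, the horizontal axis the marker genes, colour the log10 of the mean CPM of both libraries plus 1, and dot size the share of cells with at least 1 UMI of the gene. Neurog3 stood at 3147 CPM in the Neurog3+ endocrine progenitor-like class and Gcg at 7355 CPM in the alpha-like class, as means of 2 libraries.

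Trunk/duct-like cells made up 29.7% of library 1 (95% exact binomial interval 25.8% to 33.9%) and 24.7% of library 2 (22.1% to 27.4%). Neurog3+ endocrine progenitor-like cells made up 22.3% (18.8% to 26.2%) and 14.95% (12.9% to 17.2%), which differed beyond both intervals. The intervals of acinar/tip-like cells, 2.72% (1.49% to 4.52%) and 9.07% (7.41% to 10.9%), and immune-like cells, 1.94% (0.935% to 3.54%) and 6.17% (4.80% to 7.78%), were apart as well, and each share depends on the others. Fev+ endocrine precursor-like cells were 19.8% (16.4% to 23.5%) and 16.5% (14.4% to 18.9%), alpha-like cells 13.2% (10.4% to 16.4%) and 12.9% (10.9% to 15.1%), and beta-like cells 8.93% (6.61% to 11.7%) and 10.9% (9.13% to 13.0%). The intervals cover counting error only.

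Neurog3+ endocrine progenitor-like cells were set against trunk/duct-like cells to ask which genes go with entry into the endocrine programme. Insm1, a zinc-finger factor needed for endocrine differentiation, stood at 1584 ± 96.0 CPM in progenitor-like cells and 149 ± 55.0 CPM in trunk/duct-like cells (mean ± SD, n = 2 libraries), a log2 fold change of 3.42 ± 0.14 (SE; edgeR adjusted p = 4.85e-46). Hes1, the transcriptional repressor that Notch signalling induces, went the other way, from 333 ± 169 CPM in trunk/duct-like to 23.9 ± 0.524 CPM in progenitor-like cells (log2 fold change -3.77 ± 0.33, adjusted p = 5.19e-19). Its fold was -3.12 in library 1 alone and -4.16 in library 2 alone. Insm1 is on chromosome 2 (146221921 to 146225020, plus strand) and Hes1 on chromosome 16 (30064384 to 30067796, plus strand).

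Of 46 tested pancreas and endocrine transcription factor genes, 20 were higher and 7 lower in progenitor-like cells, both before and after the p-values were adjusted over the list alone, and 18 and 5 by DESeq2. The list as a whole lay toward higher values (camera adjusted p = 3.66e-08), but adjusted p = 0.0724 with an estimated correlation. Beside Insm1, the homeobox gene Nkx2-2 was higher by 2.61 ± 0.13 on the log2 scale (adjusted p = 1.58e-37), and Pax4, which favours the beta fate, and Neurod1, a direct Neurog3 target, by 3.96 and 3.49. Id2, an inhibitor of such basic helix-loop-helix factors, was lower at -3.31. In the Notch list 6 of 22 genes were higher and 5 lower (8 and 6 adjusted over the list alone, 2 and 2 by DESeq2), and the list did not pass (camera adjusted p = 0.765). The receptor gene Notch2 was lower at -2.28, as was Hes1, while the ligand gene Dll4 and Numbl, a Notch antagonist, were higher by 1.35 and 2.39.

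Secretory granule and exocytosis genes showed 19 of 46 higher and 0 lower (20 and 0 adjusted over the list alone, 16 and 0 by DESeq2). Beside that 0, edgeR gave 0 lower genes at an unadjusted p under 0.05 and DESeq2 gave 0. The camera test gave adjusted p = 5.32e-17 for the list, but adjusted p = 0.0703 with an estimated correlation. Syt13, a synaptotagmin of endocrine precursors, was higher by 2.95 ± 0.18 and Aplp1, an amyloid precursor-like gene, by 2.79 ± 0.17. Of the membrane excitability and calcium genes 8 of 33 were higher and 2 lower (10 and 2 adjusted over the list alone, 6 and 2 by DESeq2; camera adjusted p = 0.00250, and adjusted p = 0.102 with an estimated correlation). Cacna2d1, a calcium channel subunit gene, was higher by 3.44 ± 0.25, and Atp1b1, a sodium pump subunit gene, lower at -3.09 ± 0.18. Among neuronal migration and axon guidance genes, 9 of 57 were higher and 7 lower (11 and 7 adjusted over the list alone, 8 and 3 by DESeq2), and the list did not pass (camera adjusted p = 0.238). The microtubule genes Tubb3 and Map1b were higher by 3.66 ± 0.29 and 3.48 ± 0.22, and the chemokine gene Cxcl12 was lower at -2.82.

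In progenitor-like cells 33 of 50 genes of the G2/M list were lower (40 adjusted over the list alone) and 13 of 38 genes of the S phase list (18 adjusted over the list alone). Hmgb2 was lower at -1.73 ± 0.16 (adjusted p = 5.66e-17) and Pcna, the replication clamp, at -1.74. In neither list was a gene higher, with 0 at an unadjusted p under 0.05 by edgeR and 0 by DESeq2, and DESeq2 called 13 lower in G2/M and 1 in S phase. The lists had camera adjusted p = 3.48e-20 and 4.23e-07, but adjusted p = 0.0703 and 0.0561 with an estimated correlation. The trunk/duct-like class holds a cluster of cycling cells, led by cycle genes that include Ccna2 and Aspm, which are not in the lists. Cycling progenitor-like cells may have been grouped there, so the way the classes were made may set part of this difference. Without that cluster, a choice made after seeing the data, 3 of 42 G2/M genes and 6 of 37 S phase genes were lower. Of 15 cell cycle exit genes 3 were higher and 2 lower (3 and 4 adjusted over the list alone, 3 and 2 by DESeq2), with camera adjusted p = 0.676 and a median log2 fold of -0.03 against a test direction of higher. The higher ones were Btg2 (1.62 ± 0.13), Cdkn1a (1.21) and Trp53inp1 (1.95), which restrain proliferation, and the lower ones the cyclin genes Ccnd1 (-1.86) and Ccnd2 (-1.15), which drive it.

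Extracellular matrix and integrin genes were lower in 11 of 33 cases (13 adjusted over the list alone, 5 by DESeq2; camera adjusted p = 1.05e-05, and adjusted p = 0.0724 with an estimated correlation), among them the laminin genes Lamc1 (-2.05) and Lamb1 (-1.64). Of 19 Hippo/YAP genes 4 were lower and 1 higher (6 and 2 adjusted over the list alone, 3 and 0 by DESeq2; camera adjusted p = 0.0223, and adjusted p = 0.143 with an estimated correlation), including the YAP target Cyr61 (-4.58 ± 0.31) and Yap1 itself (-1.57). Wnt and planar cell polarity genes had 7 of 32 lower and 1 higher (8 and 1 adjusted over the list alone, 3 and 0 by DESeq2; camera adjusted p = 0.00943, and adjusted p = 0.144 with an estimated correlation), with the effector gene Tcf7l2 at -1.47. Glucose metabolism and glycolysis genes had 10 of 27 lower and 3 higher (11 and 3 adjusted over the list alone, 4 and 2 by DESeq2; camera adjusted p = 0.0462, and adjusted p = 0.162 with an estimated correlation). Ldha, which makes lactate, was lower at -2.67. In the list of immediate-early and heat shock genes, which also respond to cell dissociation, 11 of 24 were lower and 3 higher (13 and 4 adjusted over the list alone, 6 and 1 by DESeq2; camera adjusted p = 0.000268, and adjusted p = 0.204 with an estimated correlation), with Fosb at -2.09.

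The other lists did not pass the camera test. Junction, keratin and polarity genes had 13 of 46 lower and 6 higher (14 and 7 adjusted over the list alone, 5 and 3 by DESeq2; camera adjusted p = 0.0562), with E-cadherin gene Cdh1 at -1.54. The FGF, EGF, BMP and TGF-beta list had 8 of 28 lower and 3 higher (8 and 4 adjusted over the list alone, 2 and 2 by DESeq2), with Fgfr2 at -2.62. The epithelial-mesenchymal transition list had 2 of 9 lower (2 adjusted over the list alone, 2 by DESeq2), namely Vim (-2.13 ± 0.21) and Sparc (-0.88). Of the ER stress and protein folding genes 3 of 35 were higher and 3 lower (4 and 4 adjusted over the list alone, 3 and 0 by DESeq2), with Sel1l, a gene of ER-associated degradation, higher by 2.16 ± 0.19. Oxidative phosphorylation had 6 of 75 higher and 1 lower (3 and 0 adjusted over the list alone, 2 and 0 by DESeq2), ribosomal proteins 3 of 80 higher and 2 lower (1 and 2 adjusted over the list alone, 0 and 2 by DESeq2), and mitochondrially encoded transcripts 1 of 12 lower (1 higher and 1 lower adjusted over the list alone, 0 and 0 by DESeq2).

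Over all 9662 tested genes, edgeR called 642 higher and 620 lower at adjusted p below 0.05, 1260 of the 1262 with the same sign in both libraries. DESeq2 called 494 and edgeR with count splitting 742. Outside the lists, the largest rises were in Cabp7 (3.75), Baiap3 (3.73), Cdc14b (3.35), Fam210b (3.18), Rundc3a (2.97) and Insrr (2.93). The SEs of these 6 ran from 0.24 to 0.64, and Baiap3 stood at 2.72 in library 1 and 4.50 in library 2. Hpgd, which degrades prostaglandins, gave 0 UMIs in progenitor-like cells and 91 in trunk/duct-like cells. It was at least 13.85-fold lower by the lower 95% counting limit, and 17.4-fold lower against a floor of 3 UMIs over both libraries. Krt33a (-4.63), the connexin gene Gja1 (-4.28), Cdc42ep1 (-3.93), Bicc1 (-3.78) and Adamts9 (-3.43) followed, with SEs of 0.20 to 0.54. The folds of Krt33a were -3.11 and -5.82 and those of Gja1 -3.25 and -4.71 in libraries 1 and 2.

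Fev+ endocrine precursor-like cells were set against Neurog3+ endocrine progenitor-like cells to ask what differs once Neurog3 has fallen. Of 80 ribosomal protein genes 69 were lower in the precursor-like cells, and of 46 secretory granule genes 25 were higher, the first list passing under both forms of the list test and the second only with the preset correlation (adjusted p = 0.0548 with an estimated correlation). Chgb, which encodes the granule protein chromogranin B, stood at 4311 ± 172 CPM against 160 ± 40.5 CPM (mean ± SD, n = 2 libraries), a log2 fold change of 4.77 ± 0.12 (SE; edgeR adjusted p = 3.85e-71). Pax6, a homeobox gene of maturing endocrine cells, stood at 773 ± 135 against 115 ± 28.8 CPM (2.76 ± 0.18, adjusted p = 4.79e-28), and Sox4, expressed in early endocrine progenitors, at 279 ± 61.7 against 1788 ± 339 CPM (-2.67 ± 0.13, adjusted p = 1.05e-37). Chgb lies on chromosome 2 (132781278 to 132795079, plus strand), Pax6 on chromosome 2 (105668900 to 105697364, plus strand) and Sox4 on chromosome 13 (28948919 to 28953713, minus strand).

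Secretory granule and exocytosis genes had 25 of 46 higher and 0 lower (29 and 1 adjusted over the list alone, 19 and 0 by DESeq2). Beside that 0, edgeR gave 1 lower gene at an unadjusted p under 0.05 and DESeq2 gave 0. The camera adjusted p was 3.73e-29, and adjusted p = 0.0548 with an estimated correlation. Beside Chgb they included the prohormone processing genes Pcsk2 (3.17), Cpe (2.79) and Pam (2.66), and Gnas (1.52 ± 0.06), the stimulatory G protein gene. Excitability and calcium genes had 6 of 33 higher and 1 lower (7 and 1 adjusted over the list alone, 3 and 1 by DESeq2; camera adjusted p = 0.00382, and adjusted p = 0.106 with an estimated correlation), with the calcium pump gene Atp2a2 higher by 1.36 ± 0.15 and Abcc8, the sulfonylurea receptor gene, by 2.23. Of the transcription factor genes 16 of 46 were higher and 11 lower (16 and 13 adjusted over the list alone, 13 and 9 by DESeq2), and the list as a whole did not pass (camera adjusted p = 0.106). Meis2 and Pdx1 were higher by 2.03 and 2.26, and Insm1, Hes6 and Pax4 lower at -1.47, -1.84 and -1.79.

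Of 80 ribosomal protein genes 69 were lower in Fev+ cells and 0 higher (71 and 0 adjusted over the list alone, 56 and 0 by DESeq2), with a median log2 fold of -0.64. Beside that 0, edgeR gave 0 higher genes at an unadjusted p under 0.05 and DESeq2 gave 0. This list passed under both forms of the camera test (adjusted p = 1.74e-59, and adjusted p = 0.00520 with an estimated correlation). Rpl39 was lower at -1.14 ± 0.12 (adjusted p = 8.42e-15) and Rps3 at -1.02 ± 0.11 (adjusted p = 1.24e-14). Mitochondrially encoded transcripts had 6 of 12 lower and 0 higher (11 and 0 adjusted over the list alone, 6 and 0 by DESeq2; 0 higher with edgeR at an unadjusted p under 0.05), with a median log2 fold of -0.29 (camera adjusted p = 4.92e-11, and adjusted p = 0.0960 with an estimated correlation).

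Junction, keratin and polarity genes had 11 of 46 lower and 1 higher (14 and 1 adjusted over the list alone, 6 and 1 by DESeq2; camera adjusted p = 0.00119, and adjusted p = 0.141 with an estimated correlation), led by the claudin gene Cldn6 (-2.35 ± 0.16) and Cd24a (-1.96 ± 0.21). Extracellular matrix and integrin genes had 6 of 33 lower (6 adjusted over the list alone, 3 by DESeq2; camera adjusted p = 0.00157, and adjusted p = 0.106 with an estimated correlation), with Col18a1 at -2.98 ± 0.33. The epithelial-mesenchymal transition list had 4 of 9 lower and 1 higher (4 and 1 adjusted over the list alone, 3 and 1 by DESeq2; camera adjusted p = 0.0358, and adjusted p = 0.194 with an estimated correlation), with Sparc, a matrix glycoprotein gene, at -2.42 ± 0.18. Notch pathway genes had 6 of 22 lower and 1 higher (6 and 1 adjusted over the list alone, 3 and 1 by DESeq2; camera adjusted p = 0.0101, and adjusted p = 0.132 with an estimated correlation), among them Rbpj (-1.24), the transcription factor of the pathway. The FGF, EGF, BMP and TGF-beta list had 7 of 28 lower (9 adjusted over the list alone, 3 by DESeq2; camera adjusted p = 0.00385, and adjusted p = 0.106 with an estimated correlation), with Fgfr3 at -1.77. S phase genes had 7 of 38 lower (8 adjusted over the list alone, 2 by DESeq2; camera adjusted p = 0.00157, and adjusted p = 0.102 with an estimated correlation), with Mcm6 at -1.71. Cell cycle exit genes had 5 of 15 lower and 1 higher (7 and 2 adjusted over the list alone, 4 and 0 by DESeq2; camera adjusted p = 0.0204, and adjusted p = 0.143 with an estimated correlation), with Btg2 at -0.95 and Ccnd1, a cyclin gene that drives the cycle, at -1.64. Immediate-early and heat shock genes had 8 of 24 higher and 2 lower (9 and 3 adjusted over the list alone, 2 and 0 by DESeq2; camera adjusted p = 0.0264, and adjusted p = 0.389 with an estimated correlation), with Junb higher by 1.40.

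The remaining 8 lists did not pass the camera test, with adjusted p from 0.0562 to 0.836. Closest was Hippo/YAP, with 4 of 19 lower and 1 higher (4 and 1 adjusted over the list alone, 1 and 0 by DESeq2), among them the gene of the YAP partner Tead2 (-3.48 ± 0.30). It passed without the library block (adjusted p = 0.0434). Within the ER list Sel1l was lower at -1.92 ± 0.20, and within the neuronal list Stmn1, which destabilises microtubules, at -2.09 ± 0.23.

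In all, edgeR called 436 genes higher and 601 lower in Fev+ cells, 1034 of the 1037 with the same sign in both libraries. DESeq2 called 486 and edgeR with count splitting 677. Outside the lists Cnih2 (3.91), Fam183b (3.64), Dbpht2 (3.58), Parm1 (3.50), Entpd3 (3.42) and Gch1 (3.39) rose most, with SEs of 0.27 to 0.48. Dbpht2 stood at 2.21 in library 1 and 4.44 in library 2. Cabp7 and Slmo1 each gave 3 UMIs in Fev+ cells and 39 in progenitor-like cells, a ratio of 13.9 (95% counting interval 4.42 to 70.3). Cabp7 stood at 0 against 41.2 CPM in library 1 and at a log2 fold of -3.17 in library 2, and Slmo1 at -4.07 and -3.11 in libraries 1 and 2. Aldh1b1 (-3.42), Anxa1 (-3.28), Cacna1s (-3.18) and Plch2 (-3.12) also fell, with SEs of 0.37 to 0.63. In libraries 1 and 2 Cacna1s stood at -4.65 and -2.33 and Plch2 at -2.31 and -3.52.

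Alpha-like cells were set against Fev+ endocrine precursor-like cells to ask what separates the cluster with the most Gcg from the precursor-like class. Alpha-like cells held less Chgb, at 907 ± 63.5 CPM against 4311 ± 172 CPM (mean ± SD, n = 2 libraries), a log2 fold change of -2.25 ± 0.10 (SE; edgeR adjusted p = 7.46e-45). They held less Nkx6-1, a homeobox gene of the beta lineage, at 139 ± 29.9 against 435 ± 51.7 CPM (-1.64 ± 0.19, adjusted p = 1.80e-11). Sdhc, which encodes a membrane subunit of succinate dehydrogenase, was higher, at 513 ± 44.9 against 113 ± 16.5 CPM (2.20 ± 0.22, adjusted p = 8.36e-14). Nkx6-1 is on chromosome 5 (101658139 to 101664996, minus strand) and Sdhc on chromosome 1 (171127165 to 171150603, minus strand).

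Of 46 transcription factor genes 8 were lower and 4 higher in alpha-like cells (12 and 6 adjusted over the list alone, 5 and 3 by DESeq2; camera adjusted p = 0.00119, and adjusted p = 0.141 with an estimated correlation). Irx1 and Isl1, an Iroquois and a LIM homeobox gene, were higher by 2.63 and 0.90, and Pdx1, Nkx2-2 and Mnx1, which act in beta cells, lower at -1.83, -1.18 and -3.23. Nkx2-2 was also lower in beta-like than in Fev+ cells, so its fall was not particular to alpha-like cells. Sox4 was lower in alpha-like cells at -1.67 ± 0.20, with -2.51 in library 1 and -1.35 in library 2. Secretory granule genes went both ways, 8 of 46 higher and 3 lower (12 and 6 adjusted over the list alone, 6 and 1 by DESeq2; camera adjusted p = 0.137). Scg2 was higher by 2.37 and Gnas by 0.54 ± 0.06, while Chga was lower at -1.26.

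ER stress and protein folding genes were higher in 5 of 35 cases and lower in 0 (8 and 0 adjusted over the list alone, 2 and 0 by DESeq2). Beside that 0, edgeR gave 1 lower gene at an unadjusted p under 0.05 and DESeq2 gave 0. The median log2 fold was 0.38 (camera adjusted p = 6.12e-07, and adjusted p = 0.0561 with an estimated correlation). Calr, the ER chaperone calreticulin, was higher by 0.68 ± 0.10 and Ssr2, a translocon subunit, by 1.07 ± 0.18. Hspa5, the ER chaperone BiP, was higher by 0.54, but stood at -0.04 in library 1 and 1.08 in library 2. Ribosomal protein genes had 9 of 80 lower and 0 higher (15 and 0 adjusted over the list alone, 2 and 0 by DESeq2; 0 higher with edgeR at an unadjusted p under 0.05). The median was -0.16 (camera adjusted p = 3.10e-11, and adjusted p = 0.0561 with an estimated correlation), with Rpl28 at -0.73 ± 0.11 and Rps9 at -0.54 ± 0.11. The call of Rps9 ended without the library block. Oxidative phosphorylation had 1 of 75 higher, Sdhc, and 1 lower, Cox7a2l (1 and 1 adjusted over the list alone, 1 and 0 by DESeq2), with a median of 0.20 (camera adjusted p = 0.00452, and adjusted p = 0.143 with an estimated correlation). Mitochondrially encoded transcripts had 2 of 12 higher, mt-Nd2 (0.24) and mt-Co3 (0.23), and 0 lower (2 and 0 adjusted over the list alone, 0 and 0 by DESeq2; 0 lower with edgeR at an unadjusted p under 0.05). That list had camera adjusted p = 0.00181, adjusted p = 0.222 with an estimated correlation and adjusted p = 0.0567 without the library block.

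Immediate-early and heat shock genes were lower in 7 of 24 cases and higher in 0 (9 and 0 adjusted over the list alone, 3 and 0 by DESeq2; 2 higher with edgeR at an unadjusted p under 0.05). The list had camera adjusted p = 4.23e-07, but adjusted p = 0.141 with an estimated correlation. The stress-response gene Atf3 gave 3 UMIs in alpha-like and 74 in Fev+ cells, a ratio of 20.3 (95% counting interval 6.69 to 101), with log2 folds of -2.67 in library 1 and -5.01 in library 2. The immediate-early gene Ier2 was lower at -1.32 ± 0.25. The other 14 lists had camera adjusted p from 0.0906 to 0.953. In the S phase, G2/M, Notch, Wnt and Hippo/YAP lists edgeR called 0 genes in either direction, and 0 adjusted over the list alone. At an unadjusted p under 0.05 edgeR gave 1 higher and 2 lower in S phase, 2 and 2 in G2/M, 0 and 2 in Notch, 4 and 2 in Wnt and 1 and 0 in Hippo/YAP, and DESeq2 called 0 in each of the 5. At least 1 member of each is given by value only, Pcna at 0.01 ± 0.38, Mki67 at -1.60 ± 0.60, Dlk1 at -0.32 ± 0.15, Tcf7l2 at -0.52 ± 0.30 and Yap1 at -0.14 ± 0.43. Of the lists not passed, Btg2 was lower at -1.34 ± 0.16, Stmn1 at -1.91 ± 0.37 and Vim at -1.70 ± 0.34, the last with -2.55 in library 1 and -1.11 in library 2.

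In all, edgeR called 107 genes higher and 95 lower in alpha-like cells, 201 of the 202 with the same sign in both libraries. It called 94 without the library block and 121 with count splitting, and DESeq2 called 70. Edn3, the gene of a secreted endothelin, rose by 2.74, followed by St5 (2.40), Tmsb15b1 (2.33), Asic3 (2.21), Cage1 (2.20) and the amino acid transporter gene Slc16a10 (2.17), with SEs of 0.31 to 0.59. Tmsb15b1 shares exons with Tmsb15b2 and Tmsb15l, so its level is uncertain. Npepl1 (-2.95), Flrt1 (-2.32), Pdk3 (-2.29), Zfp703 (-2.22), Insrr (-1.80) and Stx16 (-1.78) fell, with SEs of 0.29 to 0.48, and Flrt1 stood at -1.04 in library 1 and -3.21 in library 2. The calls of Asic3 without the library block, St5 with genes scaled within each library and Insrr with called doublets kept ended. With count splitting, in which separate parts of the UMIs served clustering and testing, the calls of Asic3, Cage1, Zfp703, Insrr, Stx16 and Rps9 ended.

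Beta-like cells were set against Fev+ endocrine precursor-like cells to ask the same of the class with the insulin genes. Genes of protein folding in the endoplasmic reticulum were higher in 27 of 35 cases. Calr stood at 2856 ± 4.51 CPM in beta-like and 666 ± 37.1 CPM in Fev+ cells (mean ± SD, n = 2 libraries), a log2 fold change of 2.10 ± 0.10 (SE; edgeR adjusted p = 2.47e-40). Hspa5 stood at 2547 ± 236 against 756 ± 198 CPM (1.76 ± 0.12, adjusted p = 5.56e-27), and Slc2a2, the glucose transporter of beta cells, at 398 ± 47.6 against 59.4 ± 14.8 CPM (2.76 ± 0.27, adjusted p = 3.19e-15). Calr lies on chromosome 8 (84841850 to 84846934, minus strand), Hspa5 on chromosome 2 (34771970 to 34777547, plus strand) and Slc2a2 on chromosome 3 (28697903 to 28731359, plus strand).

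Of 35 ER stress and protein folding genes 27 were higher and 0 lower (27 and 0 adjusted over the list alone, 23 and 0 by DESeq2), with a median log2 fold of 1.26. Beside that 0, edgeR gave 0 lower genes at an unadjusted p under 0.05 and DESeq2 gave 0. The list passed under both forms of the camera test (adjusted p = 5.82e-46, and adjusted p = 0.00520 with an estimated correlation). Sdf2l1, Manf and Pdia4, which aid folding or respond to ER stress, were higher by 3.36, 1.99 and 1.86. Secretory granule genes had 15 of 46 higher and 2 lower (17 and 5 adjusted over the list alone, 7 and 2 by DESeq2; camera adjusted p = 9.22e-05, and adjusted p = 0.162 with an estimated correlation). Scg2 rose by 3.05 ± 0.28, Gnas by 0.70 ± 0.06 and Slc30a8, the zinc transporter of insulin granules, by 2.46, while Chgb was lower at -0.93. Glucose metabolism genes had 5 of 27 higher and 0 lower (6 and 0 adjusted over the list alone, 3 and 0 by DESeq2; 3 lower with edgeR at an unadjusted p under 0.05), among them Slc2a2 and Gapdh (0.73). The list had camera adjusted p = 0.0135, and adjusted p = 0.134 with an estimated correlation. Oxidative phosphorylation had 5 of 75 higher and 1 lower (9 and 1 adjusted over the list alone, 1 and 1 by DESeq2; camera adjusted p = 1.76e-06, and adjusted p = 0.0724 with an estimated correlation), with Atp5k higher by 1.07 and Cox7a2l lower at -0.93.

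Of 46 transcription factor genes 12 were lower and 4 higher in beta-like cells (15 and 4 adjusted over the list alone, 7 and 1 by DESeq2; camera adjusted p = 1.05e-05, and adjusted p = 0.102 with an estimated correlation), with Nkx2-2 at -1.29 ± 0.15 and Neurod1 at -0.91. Junction, keratin and polarity genes had 6 of 46 lower and 2 higher (6 and 2 adjusted over the list alone, 5 and 2 by DESeq2; camera adjusted p = 0.00303, and adjusted p = 0.144 with an estimated correlation). The claudin gene Cldn4 was lower at -2.13 ± 0.30, with -1.53 in library 1 and -2.53 in library 2. Ribosomal protein genes had 12 of 80 lower and 2 higher (16 and 3 adjusted over the list alone, 4 and 1 by DESeq2; camera adjusted p = 0.00385, and adjusted p = 0.141 with an estimated correlation), with Rps26 at -0.69. Mitochondrially encoded transcripts had 6 of 12 lower and 0 higher (7 and 1 adjusted over the list alone, 0 and 0 by DESeq2; 1 higher with edgeR at an unadjusted p under 0.05), with mt-Cytb at -0.30. That list had camera adjusted p = 2.88e-07, and adjusted p = 0.125 with an estimated correlation.

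Cell cycle exit genes had 2 of 15 lower and 0 higher (2 and 0 adjusted over the list alone, 2 and 0 by DESeq2; 0 higher with edgeR at an unadjusted p under 0.05), with camera adjusted p = 9.28e-05, and adjusted p = 0.0731 with an estimated correlation. They were Btg2 (-1.01) and Cdkn1a (-2.60 ± 0.23), the gene of the p21 inhibitor, which stood at -1.90 in library 1 and -2.96 in library 2. Immediate-early and heat shock genes had 7 of 24 lower and 0 higher (9 and 0 adjusted over the list alone, 3 and 0 by DESeq2; 0 higher with edgeR at an unadjusted p under 0.05), with Hsp90ab1 at -0.68 ± 0.08. That list had camera adjusted p = 5.21e-10, and adjusted p = 0.106 with an estimated correlation. The other 10 lists had camera adjusted p from 0.350 to 0.937. In the matrix and Hippo/YAP lists edgeR called 0 genes in either direction, and 0 adjusted over the list alone. At an unadjusted p under 0.05 it gave 3 higher and 3 lower in the first and 0 and 1 in the second, and DESeq2 called 0 in both. By value only, Itgb1 stood at 0.03 ± 0.20 and Yap1 at -0.01 ± 0.44. Single members that passed in lists that did not were Atp2a2 (1.59 ± 0.12), Cacna2d1 (-1.74 ± 0.22), the microtubule gene Mapt (2.73 ± 0.29) and Dlk1, a Notch ligand-like gene (1.24 ± 0.14).

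In all, edgeR called 289 genes higher and 168 lower in beta-like cells, 456 of the 457 with the same sign in both libraries. It called 263 without the library block and 289 with count splitting, and DESeq2 called 181. Syndig1l (4.26), Abi3 (3.66), Galnt18 (3.61), Spns2 (3.37), Aox1 (3.21) and Plag1 (3.14) rose most outside the lists, with SEs of 0.37 to 0.73. Syndig1l stood at 169.7 against 0 CPM in library 1 and at a log2 fold of 3.23 in library 2, and Plag1 at 2.45 and 3.76 in libraries 1 and 2. Srl (-2.13), Pdk3 (-2.10), Msi1 (-2.10), Calcoco1 (-2.02), Oxa1l (-1.99) and Dusp16 (-1.94) fell, with SEs of 0.38 to 0.56. Srl stood at 0 against 43.6 CPM in library 1 and at a log2 fold of -1.65 in library 2. In libraries 1 and 2 Pdk3 stood at -0.62 and -3.32, Calcoco1 at -3.10 and -1.53 and Dusp16 at -1.07 and -2.41. At the lower clustering resolution the calls of Calcoco1, Oxa1l and Dusp16 ended, and with count splitting those of Calcoco1 and Oxa1l ended.

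Beta-like cells were set against alpha-like cells to ask what separates these 2 classes from each other. Nkx6-1 stood at 623 ± 73.9 CPM in beta-like and 139 ± 29.9 CPM in alpha-like cells (mean ± SD, n = 2 libraries), a log2 fold change of 2.15 ± 0.19 (SE; edgeR adjusted p = 1.95e-18), and Slc2a2 at 398 ± 47.6 against 26.2 ± 0.645 CPM (3.88 ± 0.33, adjusted p = 4.69e-19). ER folding genes were higher in beta-like cells here too, with Calr at 2856 ± 4.51 against 1064 ± 70.5 CPM (1.42 ± 0.10, adjusted p = 4.49e-26).

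Of 46 transcription factor genes 9 were higher and 10 lower (10 and 13 adjusted over the list alone, 7 and 8 by DESeq2), and the list did not pass (camera adjusted p = 0.161). Mnx1 was higher by 3.60 in beta-like cells, and Isl1 and Id2 lower at -1.30 and -2.46. Of 35 ER genes 21 were higher and 0 lower (27 and 0 adjusted over the list alone, 17 and 0 by DESeq2), with a median log2 fold of 0.97. Beside that 0, edgeR gave 0 lower genes at an unadjusted p under 0.05 and DESeq2 gave 0. The list passed under both forms of the camera test (adjusted p = 1.07e-30, and adjusted p = 0.00545 with an estimated correlation), with Hspa5 higher by 1.22 ± 0.11 and Sec61b, a translocon subunit gene, by 1.49. Secretory granule genes had 10 of 46 higher and 2 lower (14 and 3 adjusted over the list alone, 4 and 2 by DESeq2; camera adjusted p = 0.00235, and adjusted p = 0.222 with an estimated correlation). Chgb was higher by 1.32 ± 0.10 and Ero1lb, an ER oxidase gene of beta cells, by 2.34 ± 0.28, and Pam was lower at -1.34. Glucose metabolism genes had 3 of 27 higher and 1 lower (5 and 1 adjusted over the list alone, 2 and 0 by DESeq2; camera adjusted p = 0.00947, and adjusted p = 0.125 with an estimated correlation), with Pkm higher by 1.08.

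Mitochondrially encoded transcripts had 8 of 12 lower and 0 higher in beta-like cells (9 and 0 adjusted over the list alone, 1 and 0 by DESeq2; 0 higher with edgeR at an unadjusted p under 0.05). The median was -0.28 (camera adjusted p = 2.87e-14, and adjusted p = 0.0724 with an estimated correlation), with mt-Co3 at -0.45. Oxidative phosphorylation had 0 of 75 higher and 1 lower, Sdhc (0 and 1 adjusted over the list alone, 0 and 1 by DESeq2; 9 higher with edgeR at an unadjusted p under 0.05). Its list lay toward higher values (median 0.16, camera adjusted p = 0.0223, and adjusted p = 0.186 with an estimated correlation). Sdhc was lower at -2.09 ± 0.24, with -2.94 in library 1 and -1.75 in library 2. Ribosomal protein genes had 2 of 80 higher and 0 lower (2 and 0 adjusted over the list alone, 0 and 0 by DESeq2; 3 lower with edgeR at an unadjusted p under 0.05). That list had camera adjusted p = 0.0266, adjusted p = 0.190 with an estimated correlation and adjusted p = 0.108 without the library block.

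Cell cycle exit genes had 2 of 15 lower and 0 higher (4 and 0 adjusted over the list alone, 1 and 0 by DESeq2; 0 higher with edgeR at an unadjusted p under 0.05), with Cdkn1a at -2.45 ± 0.24. That list had camera adjusted p = 0.0357, and adjusted p = 0.162 with an estimated correlation. Junction, keratin and polarity genes had 3 of 46 lower and 2 higher (5 and 2 adjusted over the list alone, 2 and 1 by DESeq2; camera adjusted p = 0.0106, and adjusted p = 0.186 with an estimated correlation), and the list lay toward lower values (median -0.27). The mucin gene Muc1 was lower at -2.10, with -2.75 in library 1 and -1.91 in library 2. The other 12 lists had camera adjusted p from 0.0586 to 0.955. In the Hippo/YAP list edgeR called 0 of 19 genes and 0 adjusted over the list alone, with 0 higher and 1 lower at an unadjusted p under 0.05 and 0 called by DESeq2. By value only, Yap1 stood at 0.13 ± 0.47. Members that passed in lists that did not were Atp2a2 (1.68 ± 0.13), Mapt (2.87 ± 0.31), Dlk1 (1.56 ± 0.15), Hsp90aa1 (-0.89 ± 0.12) and Hsp90ab1 (-0.62 ± 0.08).

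In all, edgeR called 240 genes higher and 142 lower in beta-like than in alpha-like cells, each of the 382 with the same sign in both libraries. It called 247 without the library block and 221 with count splitting, and DESeq2 called 143. Syndig1l gave 79 UMIs in beta-like and 2 in alpha-like cells, a ratio of 44.6 (95% counting interval 11.9 to 374). Abi3 (3.83), Cd6 (3.19), Palm3 (3.15), Zfp54 (2.89) and Galnt18 (2.85) followed, with SEs of 0.49 to 0.67, and Galnt18 stood at 3.86 in library 1 and 2.33 in library 2. Nyap1 (-2.69), Cage1 (-2.63), Edn3 (-2.61), Wnk3 (-2.56), Krt90 (-2.38) and Lmo4 (-2.35) were higher in alpha-like cells, with SEs of 0.33 to 0.69. Nyap1 stood at 0 against 55.1 CPM in library 1 and at a log2 fold of -2.04 in library 2, and Lmo4 at -1.07 and -3.15 in libraries 1 and 2. The call of Krt90 ended without the library block, and those of Cage1 and Lmo4 with count splitting.

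**Figure D2:**
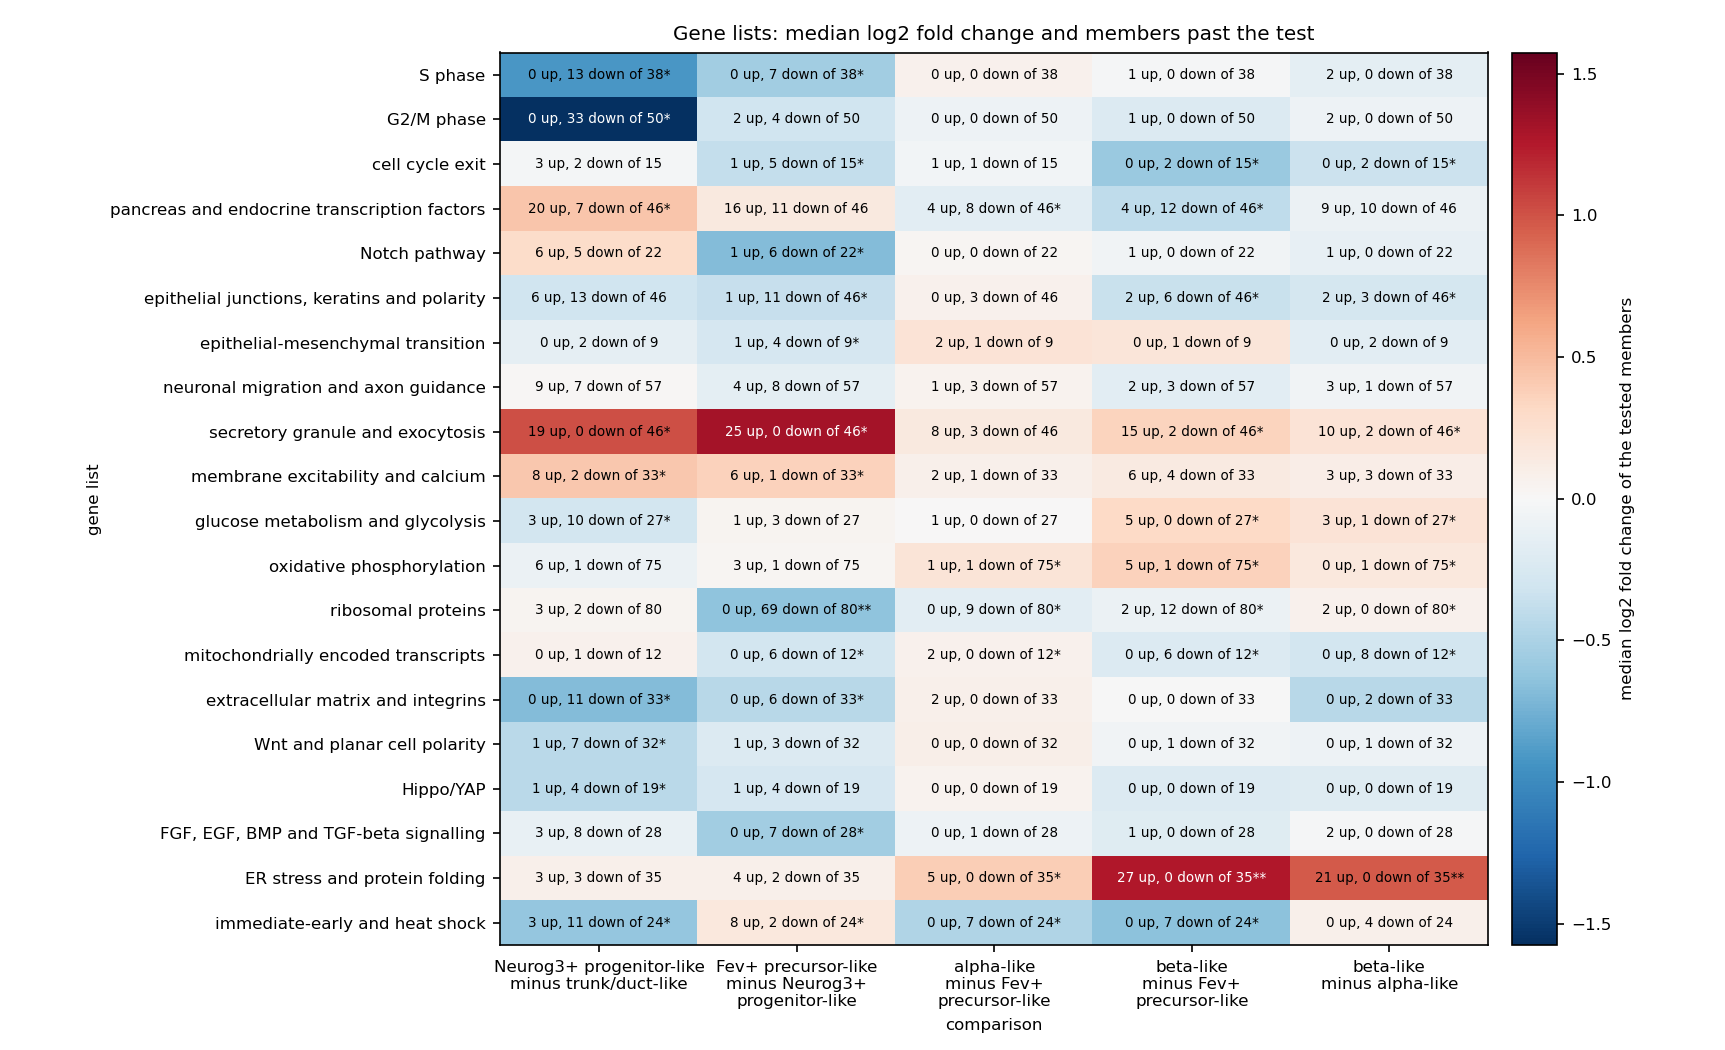
Fixed gene lists in the 5 comparisons. The vertical axis gives the 20 lists, the horizontal axis the comparisons, and colour the median log2 fold change of a list's tested genes, with the numbers of genes higher and lower at edgeR adjusted p below 0.05 printed in each field. A single star marks a camera adjusted p below 0.05 with the preset correlation, and 2 stars mark this with the estimated correlation as well. ER stress and protein folding has 27 higher of 35 in beta-like against Fev+ endocrine precursor-like cells, and ribosomal proteins 69 lower of 80 in Fev+ endocrine precursor-like against Neurog3+ endocrine progenitor-like cells.

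**Figure D3:**
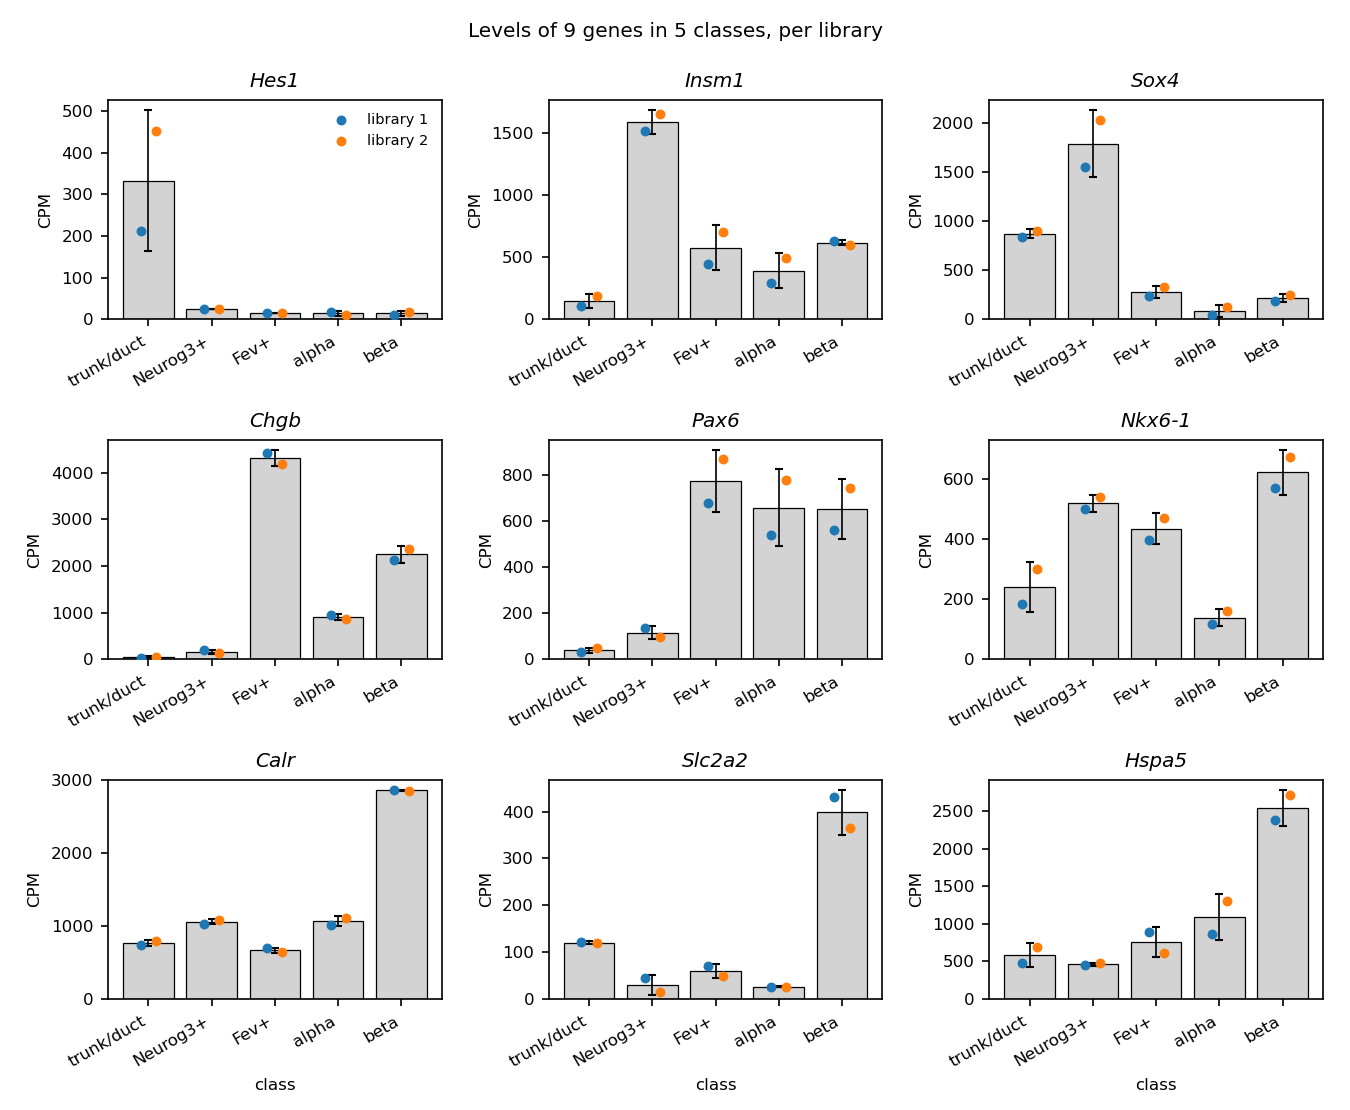
Levels of 9 genes named in the comparisons across 5 classes. Each panel is a gene, the horizontal axis gives the class, the vertical axis the level in CPM on TMM-scaled library sizes, points are the 2 libraries, bars their mean and error bars the SD. Chgb stood at 160 CPM in Neurog3+ endocrine progenitor-like, 4311 CPM in Fev+ endocrine precursor-like and 907 CPM in alpha-like cells.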

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

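The comparisons of the report left out 4 clusters, and the items here are shares of cells above the limit that a count of 0 cells allows, 0.583% of library 1 and 0.280% of library 2. Acinar/tip-like cells were 2.72% of library 1 (95% exact binomial interval 1.49% to 4.52%) and 9.07% of library 2 (7.41% to 10.9%), and immune-like cells 1.94% (0.935% to 3.54%) and 6.17% (4.80% to 7.78%). Delta-like cells were 2.34% of library 2, and 0.583% of library 1, no more than its limit. The cluster with mesenchymal and endothelial genes held 0.777% and 2.43%. Acinar/tip-like cells were set by Cpa1 at 5013 ± 965 CPM and Ctrb1 at 5812 ± 2248 CPM (mean ± SD, n = 2 libraries), immune-like cells by Csf1r at 1280 ± 52.3 CPM and C1qa at 962 ± 316 CPM, and the last cluster by Col1a1 at 3724 ± 948 CPM. The labels do not give the gate of each library, and no explanation of the shares was tested.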

How the results depend on the processing

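The numbers of genes past the test were recomputed under each alternative, in the order in which the report gives the comparisons, against 1262, 1037, 202, 457 and 382. The setting without the cycling cluster was chosen after seeing the data. With DESeq2 the numbers were 494, 486, 70, 181 and 143, and with count splitting, which tests part of the UMIs and 6324 genes, 742, 677, 121, 289 and 221. Without the replicate block (library) the last 3 comparisons gave 94, 263 and 247. The cause was not tested for DESeq2 and the block. Other settings stayed within 1.5 times the numbers above, including RLE scaling (1263, 1049, 201, 459 and 383) and no filter on low counts (1111, 866, 154, 371 and 322). The lists past camera were 10, 12, 6, 10 and 8, and with the estimated correlation 0, 1, 0, 1 and 1. Higher correlation alone does not account for this, since the forms also differ in degrees of freedom. These come from the number of genes with the preset and from the 4 residual ones with the estimate. The ER list, with an estimate of -0.0174 below the preset 0.01, went from camera adjusted p = 5.82e-46 to 0.00520 in beta-like against Fev+ cells. Estimates of other lists, such as G2/M at 0.0805, lay above the preset. The share of Fev+ endocrine precursor-like cells was 32.3% at Leiden resolution 0.6, where no alpha-like class formed and its 2 comparisons could not be made, and 20.6% with count splitting, where no delta-like class formed. The share of alpha-like cells was 14% at 2000 UMIs per cell, 12.4% with called doublets kept, 13.7% at resolution 1.6, 13.3% with genes scaled within each library and 14.2% with count splitting, and the cause was not tested. Of the 130 named results, 0 reversed under any setting. RLE scaling, no filter, 2 classes only, 2000 UMIs, resolution 1.6 and no cycling cluster kept all 130. Where cells were clustered anew, each new cluster took the main class of most of its cells, so finer clusters were merged back. At resolution 1.6, 98.4% of cells kept their class, and leaving out the cycling cluster changed only the trunk/duct-like sums. No block kept 127, and count splitting kept 112 of 122. DESeq2 called 100 of the 130 and gave no adjusted p for the rest. Called list members and the named genes outside the lists made 825 results together. Of these DESeq2 kept 476 of the 736 with an adjusted p, and no block kept 617, all in the same direction. With 1 replicate left out no residual degrees of freedom remain, so only folds can be given. Of the 130, 129 without replicate 1 and 122 without replicate 2 stayed within the larger of their SE and the SD of the 2 libraries' folds. That limit widens where the libraries disagree, so these numbers do not show that the libraries gave similar folds. The fold of Hspa5 in alpha-like against Fev+ endocrine precursor-like cells ran from -0.0402 without replicate 2 to 1.08 without replicate 1, and the cause was not tested. Depth limits the tests most below 50 CPM, where the self-test recovered 1.72% of 2-fold changes.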

Other observations

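The tests of Neurog3 in trunk/duct-like cells and of free Ghrl RNA were chosen after the result was seen. Classes outside the comparisons held programmes of their own. Acinar/tip-like cells held the acinar marker genes Pnliprp1 at 4093 ± 1158 CPM (mean ± SD, n = 2 libraries) and Clps at 1991 and 4795 CPM in libraries 1 and 2, with the acinar factor genes Ptf1a at 127 ± 9.96 CPM and Bhlha15 at 157.5 ± 14.8 CPM. Ribosomal protein transcripts took 11.05 ± 0.44% of their UMIs, against 8.21 ± 0.44% in Neurog3+ endocrine progenitor-like cells, 5.60 ± 0.35% in Fev+ endocrine precursor-like cells, 4.80 ± 0.24% in alpha-like cells and 4.87 ± 0.16% in beta-like cells. Immune-like cells held the macrophage genes Mrc1 at 1060 and 2612 CPM and Lyve1 at 610.4 and 2471 CPM in libraries 1 and 2, with 10 such cells in library 1, and the chemokine genes Ccl2 at 524 ± 105 CPM and Cxcl2 at 1279 ± 281 CPM. Delta-like cells held Hhex, a repressor needed for the delta fate, at 702 ± 180 CPM and Arg1 at 575 ± 102 CPM. Library 1 had 3 delta-like cells with 13924 UMIs, so its delta-like values rest on few counts. ER stress and protein folding genes took 1.23 ± 0.20% of UMIs in delta-like, 1.86 ± 0.10% in beta-like and 0.891 ± 0.091% in alpha-like cells. In alpha-like against Fev+ cells, Sdhc rose by 2.20 ± 0.22 (log2) while the other subunits of its complex did not pass, with Sdha at 0.44 ± 0.27, Sdhb at 0.45 ± 0.38 and Sdhd at 0.16 ± 0.33.

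Neurog3 UMIs were found in trunk/duct-like cells. At 1500 UMIs per cell, 23.9% of these cells in library 1 (95% interval 17.1% to 31.9%) and 29.4% in library 2 (23.7% to 35.6%) held 1 or more, against 13.0% (2.78% to 33.6%) and 2.60% (0.712% to 6.52%) of acinar/tip-like and immune-like cells. Free RNA alone is excluded in library 2, and in library 1 it cannot be told apart, because the intervals overlap. Progenitors or doublets grouped with these cells stay open as well: Neurog3 reached 11.6% of its progenitor level, amid the other progenitor markers, which ran from 3.89% (Cck) through 11.6% (Tox3) to 42.0% (Amotl2), and early progenitors need not have the average profile. No biological explanation was tested, since there is 1 group.

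Gcg and Ghrl fell in 1 cluster. The Ghrl level of alpha-like cells was at least 14.9 times that of any other fitted class in each library, which argues against free RNA as the source of that class level. Ghrl was also a leading gene of this cluster, and a class mean does not show whether cells with Gcg hold Ghrl of their own. Free RNA is thus not excluded for cells with both. Cells with at least 5 UMIs of both hormones had 0.935 times the UMIs of cells with at least 5 of only 1 of them in library 1 and 0.866 times in library 2, which argues against doublets. At this limit, cells with both numbered 5 against 5.35 expected by chance in library 1 and 10 against 12.1 in library 2, a ratio of 0.824 (95% interval 0.402 to 1.47), with 32 of 68 and 63 of 138 alpha-like cells holding neither, so separate Gcg and Ghrl cells and cells with both cannot be told apart. No biological explanation was tested.

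Ribosomal protein transcripts were lower in Fev+ endocrine precursor-like than in Neurog3+ endocrine progenitor-like cells. The folds here use plain CPM with a pseudocount of 1 in each library, where the edgeR fit with TMM scaling gave a median of -0.64. The median log2 fold over 80 genes was -0.57 without the 50 most abundant other genes, -0.57 in cells of low S and G2/M share and -0.53 in cells of similar depth (from 2000 UMIs up to a limit), against -0.55 in all cells, as means of 2 libraries. This argues against a few abundant genes, fewer cycling cells and depth per cell as the whole cause. Other technical causes may remain, and no biological explanation was tested.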
